A study of Mus musculus with 6 samples.

How the data were processed

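Total RNA from 6 mouse livers was amplified to biotin-labelled cRNA, hybridized to 1-colour arrays and stained with Alexa-647 streptavidin, per the labels' protocols. The groups were wild-type (3 arrays) and Src-transgenic (3 arrays), as the labels give them. Scanner and image software are not given in the sources used here. The deposited intensity of each spot was the signal after background was taken out, per the file headers, on a linear scale with 27 to 103 mouse probes per array at or below 0. A second deposited intensity column was the same signal divided by 1 constant per array. The authors' value table held that second column, equal within 1e-06 for all 34967 mouse probes on every array, so its scale and direction are known and its column medians were 0.99 to 1.00. No spot flags, slide, scan date or separate background were among the columns used here.

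Each array had 35587 spots, of which 620 were bacterial control spots of 12 names and were left out. Values under the 1st percentile of an array's positive signals were raised to it, which was 4.72 to 5.75, and log2 values were quantile normalized between arrays. Since the column was already background-corrected, no normexp correction was made and no filter on dim probes was applied. Probes carry sequence accessions, which were matched without versions to the RefSeq table of assembly GRCm38.p6, used for names and gene order only. It named 14763 probes to 13971 genes, and 20204 probes stayed unnamed here. For a gene with several probes, the one with the highest mean log2 signal was used. A probe was called above background on an array when its signal exceeded the median plus 3 scaled median absolute deviations of the 570 control spots other than those of the bright control. That threshold was 33.0 to 50.6 and was set after the data were seen. For a gene not above background on any array of a group, a fold is a bound on the difference of group means. It sets the mean of the brighter group against a raised value of the dim group. That value is the higher of the dim probe's own value and the lowest signal above background on each array. The bound leaves out the spread between arrays, so the groups may still overlap.

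Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over 34175 features). The SE of a log2 change is limma's moderated one. Gene lists, 36 with 566 tested genes, were tested with camera at a preset correlation of 0.01 against all named genes, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance. With the estimated correlation 0 lists were called. By fry 0 lists were called in one direction, and 1 for change in either direction, the metallothionein list (adjusted p = 0.018). A camera p at the preset correlation treats a list's genes as almost independent. It is too small where those genes vary together between mice. Of the 10 splits of the 6 arrays into 3 and 3, 4 gave at least 6 called lists, the real split included. The lists, the tests and the rule for named genes were set before the data were examined. The rule named Src, Mt1 and Mt2, then genes past the threshold or, with fewer than 10 of these, those with the smallest p up to 20, then up to 4 members of each list with the smallest p. The steps were tested on simulated data with the spread of these 34175 features. Of 50 genes planted at each size, 2% were recovered at a log2 change of 1, 40% at 2, 82% at 3 and 92% at 5. There were 10 false calls, and 0 calls were made when nothing was planted. All 200 planted genes changed at once, in independent noise without patches. Many true changes loosen the adjusted threshold, so these rates do not apply where few genes change. In the real data Mt2, with a log2 change of 4.88, had a limma adjusted p of 0.35. Counts of 0 therefore do not show that large changes are absent.

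Patches were sought after the data were seen. For each spot and array the median deviation of the spots within 4 rows and columns was taken, and a patch was where it exceeded 0.5 either way. Alternatives were other background offsets, scalings, filters and spread models, array weights, each array left out in turn, the authors' table and corrections for patches. Figures were drawn with matplotlib 3.10.9.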

Results

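Gene expression was measured in the livers of C57BL/6 mice aged 14 months, on 1-colour oligonucleotide arrays hybridized with biotin-labelled cRNA made from total RNA. There were 3 arrays from wild-type mice (replicates 1, 2 and 4) and 3 from mice carrying a human c-Src transgene behind the mouse metallothionein promoter (replicates 1, 3 and 4). c-Src is a non-receptor tyrosine kinase and proto-oncogene. The labels number the transgenic samples as separate mice and the wild-type samples as separate controls. The study left out 2 further arrays, wild-type sample 3 and transgenic sample 2, for low signal. Its stated purpose was to look for genes downstream of Src in livers of a line that develops liver tumours, and the labels do not say whether the sampled tissue held tumour. Each array held 34967 mouse probes. The median probe signal was 53.8, 77.0 and 93.4 on the wild-type arrays and 94.8, 111 and 117 on the transgenic arrays, so every transgenic array was brighter than every wild-type array. Between 62.6% and 71.7% of the probes lay above background on an array, a threshold that some bacterial control spots passed too. The number of arrays limits the precision of every comparison.

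The comparison of transgenic with wild-type livers began with Src itself, which checks the labels. The Src probe read 6.83 ± 0.33 (SD, n = 3) on the log2 scale in wild-type and 8.62 ± 0.99 (SD, n = 3) in transgenic livers, a log2 difference of 1.79 ± 0.51 (SE), or 3.47-fold. All 3 transgenic arrays lay above all 3 wild-type arrays, with signals of 277 to 870 against 60.8 to 127. The difference did not pass limma's test over all features (adjusted p = 0.69). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 arrays against 3 allow. The array is a mouse design with 1 probe for Src, and the sequence of that probe was not used here, so whether it reads the human transcript is unknown.

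**Figure D1:**
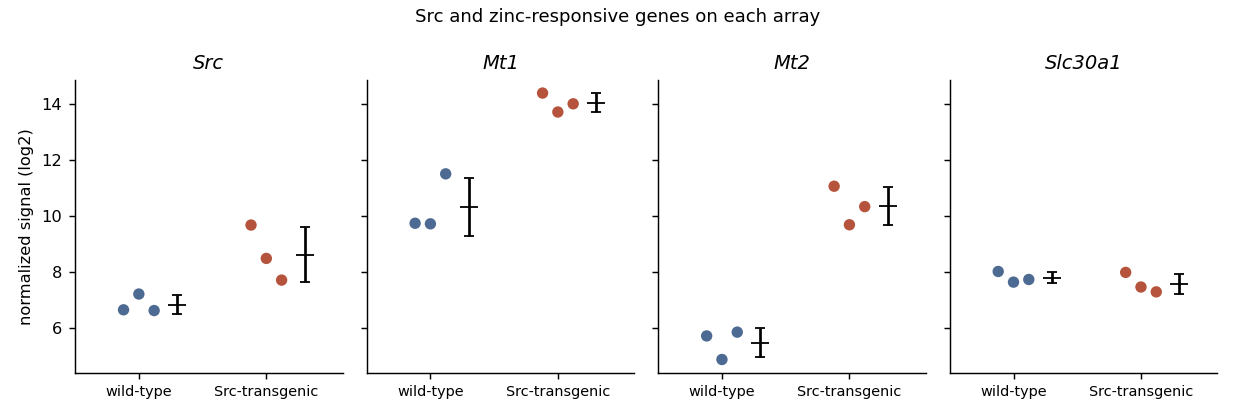
Normalized log2 signal (vertical axis) of Src, Mt1, Mt2 and the zinc exporter gene Slc30a1 on the 3 wild-type (blue) and 3 Src-transgenic (red) arrays, 1 point per array, with the group mean and SD as black bars. The groups do not overlap for Src, Mt1 and Mt2, and the Slc30a1 means differ by -0.22.

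The endogenous metallothionein genes, which encode small zinc-binding proteins and whose promoter drives the transgene, separated the groups. Mt2 read 5.48 ± 0.53 in wild-type and 10.4 ± 0.69 in transgenic livers (SD, n = 3 each), a log2 difference of 4.88 ± 0.44 (SE), or 29.4-fold, and it was above background on 2 of the 3 wild-type arrays. Mt1 read 10.3 ± 1.02 and 14.0 ± 0.34, a log2 difference of 3.71 ± 0.53, or 13.1-fold. Over all features limma's adjusted p was 0.35 for Mt2 and 0.69 for Mt1, and adjusted over the list alone both passed (1.7e-04 and 0.0012). These were 2 of the 7 tested members of the metallothionein and zinc handling list, against 0 adjusted over all features. The list as a whole was higher in transgenic livers (camera, adjusted p = 0.0081), with a mean log2 change of 1.39 and a median of 0.38. The zinc transporter genes gave small values, Slc39a14 0.53 ± 0.47, Slc39a5 0.34 ± 0.38 and Slc30a1 -0.22 ± 0.25 (SE). Leaving out single arrays gave 0.23 to 1.07 for Slc39a14, which lay in a patch on 1 array, and 0.10 to 0.73 for Slc39a5. The list call was lost with an estimated correlation (adjusted p = 0.69) and among probes above background on all 6 arrays (adjusted p = 0.079), a filter that removes Mt2.

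Among the Src family kinases, Src and Blk passed when limma's p was adjusted over the list alone (adjusted p = 0.042 and 0.0067). These were 2 of 7 tested members, against 0 adjusted over all features (0.69 for each). Adjustment over a list alone does not allow for the number of lists. Blk, a kinase of B cells, was not above background on any wild-type array and was above it on 2 transgenic arrays, at least 1.22-fold higher. Yes1 had a log2 change of -0.44 ± 0.22 and Lck -0.25 ± 0.22 (SE), the latter -0.11 without transgenic replicate 3. The list was not called (adjusted p = 0.71), and its test pointed higher with a mean of 0.45 while its median was -0.12. Src substrates and focal adhesion genes were not called either (adjusted p = 0.70), with Met at 0.51 ± 0.22, Stat3 at 0.51 ± 0.22 and Bcar1 at -0.52 ± 0.23 (-0.32 after local correction of patches). The other Stat3 probe gave 0.17 ± 0.27. Of the STAT3 and MYC target growth genes, Junb had a log2 change of 1.14 ± 0.33 and Myc 1.31 ± 0.53 (0.76 without transgenic replicate 1), and the list of 17 tested genes was not called (adjusted p = 0.29).

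Over all 34175 features, which were 13971 named genes and 20204 unnamed probes, limma called 0 genes higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1493 higher and 931 lower, together 7.09% of the features. The higher share of these was 61.6%, and median scaling in place of quantile normalization turned the split to 943 higher and 1311 lower. The groups did not overlap for 16% of the features, where chance gives 10%. The 20 named genes with the smallest p did not pass. After Mt2 and Mt1 they included Acnat2, at 2.07 ± 0.38, Tmc2, at -2.16 ± 0.23, and Lrrn4cl, at least 7.10-fold lower and not above background on any transgenic array. Tmc2, Lrrn4cl, Zc3h6, Spag16, Zfp944 and Ryr1 each lay in a bright or dim patch on 1 array and Ctps on 2. The probes used for Ptpn13, Col8a1, Prps1l1, Tmprss12, Sprr3, Ryr1 and Olfr1240 were among the 20 but not above background on any array, and both other Ryr1 probes gave negative log2 changes. Lrrc46, Zc3h6, Spag16 and Olfr1297 were above background on some arrays of 1 group alone, and Yae1d1, Zfp944 and Ctps had log2 changes of -1.12, -1.50 and -0.88. After local correction of patches Tmc2 had -1.30, Zfp944 -0.39 and Ctps 0.27, the last with its direction turned. Among unnamed probes the smallest p belonged to GE1527057, at least 2.42-fold higher, and GE1433796, at least 2.18-fold higher. On the lower side were GE1505298, at least 1.75-fold lower, and GE1575558, at least 7.44-fold lower. GE1527057 lay in a patch on 2 arrays, GE1433796 and GE1505298 on 1 each and GE1575558 on none.

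When every probe was tested separately, 1 probe passed, an Ang probe chosen here after its values were seen. Ang encodes angiogenin, a secreted ribonuclease. The probe was not above background on any wild-type array and read 12.2 to 12.3 on the 3 transgenic arrays, at least 103-fold higher (limma adjusted p = 0.0027). The brighter Ang probe, which stands for the gene elsewhere, carries the same transcript accession and differed by 0.47 ± 0.29.

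Genes with sex-biased expression in mouse liver shifted as groups. The female-biased list was higher in transgenic livers (camera, adjusted p = 7.7e-07), with positive values for 16 of 16 tested members and a median log2 change of 1.69. Adjusted over the list alone, 2 members passed, the steroid hydroxylase gene Cyp2b9 at 4.00 ± 0.83 and the peroxisomal hydroxyacid oxidase gene Hao2 at 2.61 ± 0.59 (SE), against 0 over all features. Cyp2b13 had 3.30 ± 1.19, and the estrogen sulfotransferase gene Sult1e1, not above background on any wild-type array, was at least 1.25-fold higher. The groups overlapped for Sult1e1, which read 4.65 on transgenic replicate 4 and 4.92 on wild-type replicate 1. Without transgenic replicate 1 the log2 change of Sult1e1 went from 1.81 to 1.03. The male-biased list was lower (camera, adjusted p = 7.2e-05), with negative values for 12 of 13 tested members and a median of -1.0. Its members with the smallest p were Ugt2b38 at -2.16 ± 0.59, Hsd3b5 at -2.60 ± 0.77, the organic anion transporter gene Slco1a1 at -1.58 ± 0.60 and Hsd17b2 at -0.79 ± 0.32, none of which passed over all features or over the list alone. Ugt2b38 and Slco1a1 lay in a patch on 1 array each, and local correction brought Ugt2b38 to -0.98. Both calls were lost with an estimated correlation (adjusted p = 0.69 for each) and with fry (adjusted p = 0.58 for each). Several members belong to families of close paralogs whose transcripts the probes may not separate.

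Transgenic replicate 4 stood apart on these genes. The Y-linked genes Ddx3y, Eif2s3y and Uty were not above background on that array and were above it on the other 5. Kdm5d, the remaining Y-linked gene tested, read 9.03 there against 8.32 to 8.74 elsewhere. The mean of the female-biased list minus that of the male-biased list was -4.27 to -4.13 on the wild-type arrays, -2.10 and -3.06 on transgenic replicates 1 and 3, and 1.70 on replicate 4. The labels do not give the sex of any mouse. Without replicate 4 both lists were still called, at adjusted p = 9.9e-06 for the female-biased and 3.0e-04 for the male-biased genes, with mean log2 changes of 0.95 and -0.69 in place of 1.91 and -1.16. Cyp2b13 had 1.93 and Slco1a1 -0.95 without it. The sex chromosome list had 4 tested genes and was not called (adjusted p = 0.92).

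**Figure D2:**
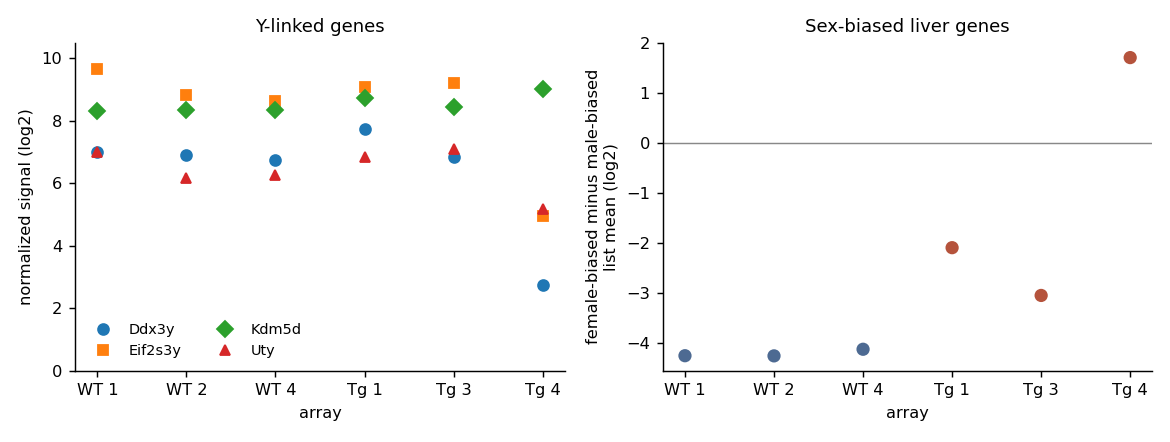
Left, normalized log2 signal of 4 Y-linked genes on each array (WT, wild-type; Tg, Src-transgenic; the number is the replicate). Right, mean log2 signal of the female-biased list minus that of the male-biased list on each array, which is 1.70 on transgenic replicate 4 and at most -2.10 on the other 5 arrays.

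Immediate early and heat shock genes, which respond within minutes to stress and growth signals, were higher as a list (camera, adjusted p = 7.2e-05), with positive values for 15 of 16 tested members and a median log2 change of 0.76. The heat shock cochaperone gene Dnajb1 had 2.28 ± 0.67, Hsp90aa1 1.29 ± 0.44 and the AP-1 gene Junb 1.14 ± 0.33 (SE), and Hsph1, not above background on any wild-type array, was at least 1.86-fold higher. The groups overlapped for Hsph1, which read 5.70 on transgenic replicate 4 and 5.71 on wild-type replicate 1. Without transgenic replicate 1 the log2 change of Hsph1 went from 1.02 to 0.66. None of the 16 passed alone. The shift was uneven, with a list mean above the wild-type mean by 1.83 in transgenic replicate 1, 0.47 in replicate 3 and 0.13 in replicate 4, the last inside the wild-type range of -0.20 to 0.16. Acute phase genes, secreted by hepatocytes in inflammation, were higher as well (camera, adjusted p = 7.2e-05), with positive values for 18 of 19 and a median of 0.40. Fgl1 had 1.32 ± 0.31, Orm2 1.22 ± 0.41, Itih4 0.62 ± 0.21 and the serum amyloid gene Saa2 0.91 ± 0.37, and none passed alone. Saa2 had 0.58 without wild-type replicate 4, and Orm2, in a patch on 1 array, had 0.81 and Saa2 0.60 after local correction. The acute phase shift was 0.57, 0.36 and 0.54 on transgenic replicates 1, 3 and 4. With an estimated correlation neither list was called (adjusted p = 0.69 for each).

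Genes of the unfolded protein response and endoplasmic reticulum stress were higher as a list (camera, adjusted p = 0.028), with positive values for 13 of 17 tested members and a median of 0.29. The list mean lay above the wild-type mean by 0.73 and 0.46 on transgenic replicates 1 and 3 and below it by 0.13 on replicate 4, where the wild-type arrays ran from -0.32 to 0.22. Creld2 had a log2 change of 1.42 ± 0.44, the chaperone gene Hspa5 1.07 ± 0.40, Dnajb9 0.89 ± 0.38 and Herpud1 0.65 ± 0.29 (SE), the last 0.42 without transgenic replicate 3. The call was lost with an estimated correlation (adjusted p = 0.78), with median scaling (0.057) and among probes outside patches of unusual brightness (0.058). It was also lost without wild-type replicates 1 and 4 (0.053 and 0.20) and without transgenic replicates 1 and 3 (0.29 and 0.095).

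**Figure D3:**
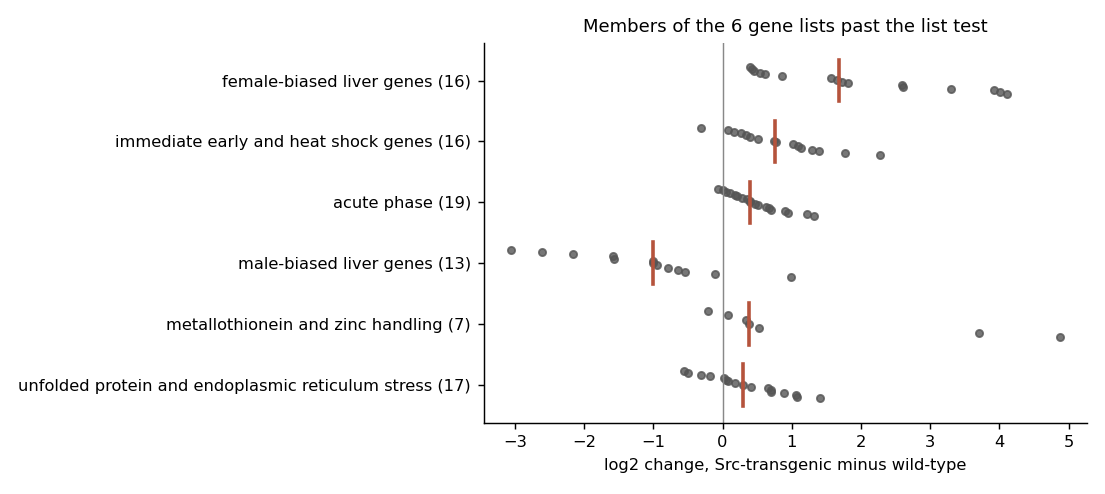
Log2 change, Src-transgenic minus wild-type, of each tested member (grey points) of the 6 lists called by camera, with the number of members in parentheses and the list median as a red bar. Medians run from -1.0 for the male-biased list to 1.69 for the female-biased list.

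Interferon and antigen presentation genes gave mostly negative values without a call. The interferon response list had 14 of 18 negative members and a median of -0.38 (adjusted p = 0.068), with Irgm1 at -0.54 ± 0.27 and Psmb9 at -0.51 ± 0.26. After local correction Psmb9 had -0.33 and Irgm1, in a patch on 3 arrays, turned to 0.30. Without transgenic replicate 3 Irgm1 had -0.32. Major histocompatibility class II genes had 6 of 7 negative members and a median of -0.67 (adjusted p = 0.077), with H2-Aa at -0.80 ± 0.36 and Cd74 at -0.67 ± 0.34, the latter -0.40 without transgenic replicate 3. Without transgenic replicate 4 both were called lower (3.0e-04 and 4.3e-04), and class II was called without wild-type replicate 2 as well (0.034) and among probes outside patches (0.025). Array weights brought a call of lower for the interferon list (0.022). Markers of T, B, plasma and natural killer cells were not called (adjusted p = 0.23), with Cd3g at -0.74 ± 0.29 and Nkg7 at -0.56 ± 0.22 (-0.35 after local correction). Macrophage and Kupffer cell markers (0.75) and neutrophil markers (0.39) were not called. Without transgenic replicate 4 the macrophage list was called lower (0.028).

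Lists of liver metabolism were not called. For fatty acid oxidation and PPAR alpha targets the adjusted p was 0.070 and the median 0.22, with Cyp4a14, a fatty acid omega-hydroxylase gene, at 1.61 ± 0.36. This list was called higher among probes above background on all 6 arrays (0.029), with a trended spread (0.032) and without transgenic replicate 1 (0.0057). Bile acid synthesis and transport had an adjusted p of 0.13 and a median of -0.22, with Nr0b2, which encodes the repressor SHP, at -1.53 ± 0.39 and Cyp39a1 at 0.94 ± 0.27. Median scaling brought a call of lower for bile acid genes (0.0022), as did leaving out transgenic replicate 3 (0.027), and median scaling did the same for the mitochondrial respiratory chain (0.0098). Xenobiotic metabolism (0.26), fatty acid synthesis and lipid storage (0.70), cholesterol synthesis (0.92), glucose metabolism (0.80), NRF2 targets (0.92), circadian clock genes (0.70), mitochondrial respiratory chain (0.71) and cytosolic ribosomal proteins (0.73) had larger adjusted p. Mean and test pointed in different directions for cholesterol synthesis and NRF2 targets, and median and test did so for cholesterol synthesis and glucose metabolism. Without transgenic replicate 4 fatty acid synthesis was called higher (0.028).

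Lists on growth and on cell types were not called either. The adjusted p was 0.70 for cell cycle genes, with Cdkn1a at 2.22 ± 0.96, Ccnb2 at -1.10 ± 0.53, Foxm1 at 0.44 ± 0.21 and Mcm6 at -0.51 ± 0.29. Cdkn1a, in a patch on 1 array, had 1.30 without transgenic replicate 1, and it read 5.45 on transgenic replicate 4 against 5.96 on wild-type replicate 1. Ccnb2 had -0.72 without transgenic replicate 3, and Mcm6, in a patch on 1 array, -0.29 without transgenic replicate 4 and -0.26 after local correction. The adjusted p was 0.71 for fetal liver and liver tumour markers, where Gpc3 had the smallest p but was above background on no array, with Tff3 at -0.69 ± 0.24 and Mbl2 at 0.56 ± 0.20, where the mean was -0.09 and the test pointed higher. Hepatocyte secreted and identity genes had an adjusted p of 0.70 and a median of 0.06, and median scaling turned this list to a call of lower (0.0022). Cholangiocyte and progenitor markers (0.75), stellate cell and matrix genes (0.39), endothelial markers (0.18), gallbladder and intestinal epithelium (0.29), exocrine pancreas (0.88), adipose tissue (0.70), smooth and skeletal muscle (0.75) and blood cell transcripts (0.92) completed the 36 lists. The gallbladder and intestinal list was called higher among probes above background on all 6 arrays (0.049). Loxl1, not above background on any transgenic array, was at least 1.58-fold lower.

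The arrays differed among themselves in ways the groups do not explain. Pairwise correlations of log2 signal across features were 0.88 to 0.92 within wild-type, 0.87 to 0.92 within transgenic and 0.86 to 0.94 between the groups. Features are not independent replicates. Bright streaks crossed several arrays. Bright and dim patches together held 0.73% of probes on transgenic replicate 1 and 7.55% on replicate 3, and 18.4% of probes lay in a patch on at least 1 array. Of the 505 features with a log2 change over 2 either way, 72.3% lay in a patch. The probes for Src, Mt1, Mt2, Cyp2b9, Hao2 and Ang lay outside patches on all 6 arrays.

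**Figure D4:**
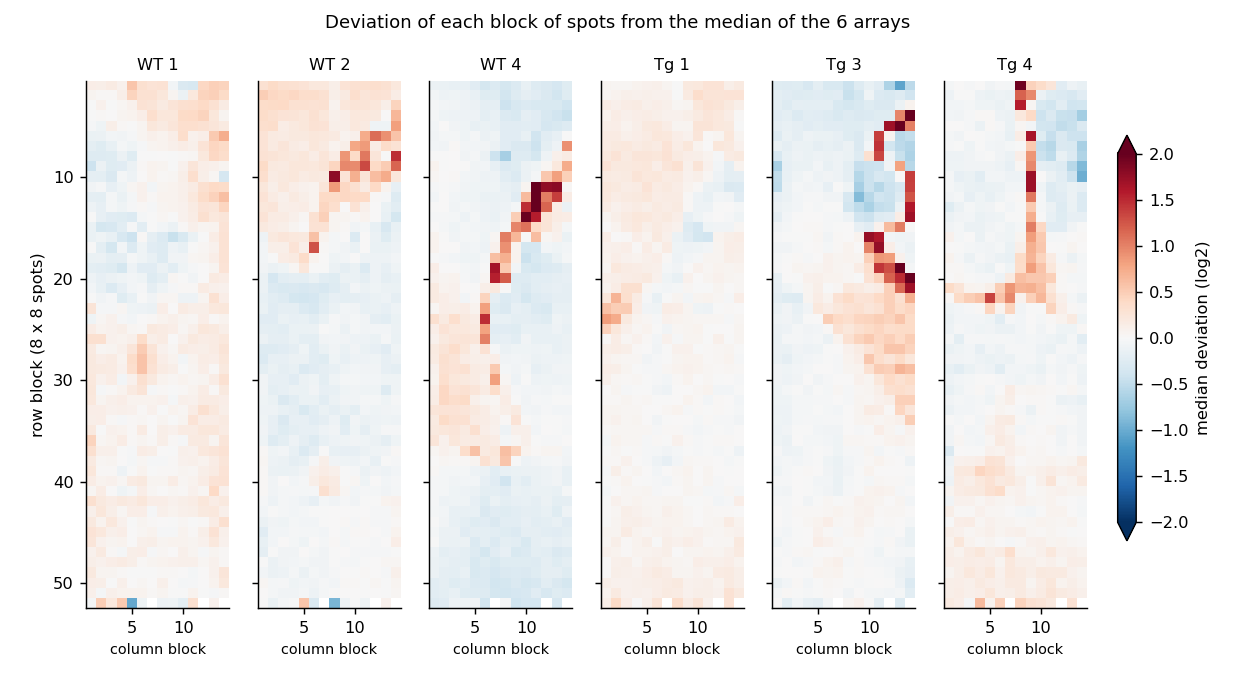
Median log2 deviation of blocks of 8 by 8 spots from each probe's median over the 6 arrays, by position on the array (horizontal axis, column block; vertical axis, row block; WT, wild-type; Tg, Src-transgenic). Red bands cross wild-type replicates 2 and 4 and transgenic replicates 3 and 4, and the brightest block reached 4.02 on wild-type replicate 4 against 0.73 on wild-type replicate 1.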

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

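The control spots named ENTF read a median signal of 29520 over the 6 arrays, a signal in spots that no comparison used, while the other 11 control names read medians of 10.8 to 56.8. On the single arrays the ENTF median was 28847 to 32812, highest on wild-type replicate 1, the dimmest array.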

How the results depend on the processing

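Filters for patches, the filter for at least 3 arrays, an added offset of 50 and the test against all probes were chosen after the data were seen. The counts of 0 genes higher and 0 lower kept their value under all alternatives except 3 fits. Testing every probe separately gave 1 higher (Ang). Without single replicates the higher count ranged from 0 to 1, the 1 being unnamed GE115078 without transgenic replicate 4, and the lower count from 0 to 1, the 1 being unnamed GE1410659 without wild-type replicate 1. The 6 called lists became 0 with an estimated correlation and 0 with fry. Both take account of how a list's genes vary together between arrays, which the preset correlation almost leaves out. How much of the loss this explains was not tested. Leaving out single replicates gave 5 to 10 lists, with 10 without transgenic replicate 4, and the other alternatives 6 to 8. The log2 change of Src stayed positive, 1.44 to 2.06 over the alternatives and 1.27 to 2.26 without single replicates, with adjusted p of 0.57 to 1.00. With camera at the preset correlation, female-biased, male-biased, acute phase and immediate early lists were called under all 14 alternative fits and 6 leave-one-out fits. These fits did not vary the list test, and none of these lists was called with an estimated correlation or with fry. All alternatives were followed for Mt1, Mt2, the 20 genes with the smallest p and the named members of the called lists. Of these, 2 values reversed and the cause was not tested. Ryr1 was -0.18 among probes outside patches, where another probe stands for it, and Ctps was 0.27 after local correction. Members of lists not called also changed sign after local correction, Irgm1 to 0.30, Mvk to 0.18, Taldo1 to 0.11, Robo4 to -0.15 and Uqcrfs1 to 1.08. Some others, such as Lep and Cox5a, did so without 1 array.

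With the replicate block, in which numbers 1 and 4 are shared, 0 genes were called higher, 0 lower and 6 lists, and Src was 2.06. Deviations of same-numbered arrays correlated at 0.06 for both numbers. Differently numbered arrays were not compared in this way, so the value does not decide whether the numbers pair the samples. Fits without background correction and with slide or scan date could not be run on these columns, and plain subtraction with a floor and no dim filter are the settings reported. Signal over background limits the dim probes, since 6764 of the mouse probes lay above it on no array.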

Other observations

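The tests of transgenic replicate 4, of replicates 1 and 3 without it, of Mt1 and Mt2 and of the Ang transcript and its patches were chosen after the results were seen, as were the gene families. Of 221 families of genes sharing a symbol stem, 6 passed camera's test. The 582 olfactory receptor genes were higher by a mean log2 change of 0.15 (adjusted p = 9.2e-04). Their mean was 0.09 with median scaling, 0.11 with cyclic loess and 0.17 outside patches. Of these genes 68 were above background on no array, against 6764 of all 34967 mouse probes. The threshold rests on control spots, so passing it does not show expression in liver. Every transgenic array was brighter than every wild-type array, and whether this shifted dim probes and with them the families was not tested. Prolactin family genes (21 genes, 0.50, adjusted p = 0.0051), Dnajb cochaperones (11 genes, 0.74, 0.0069), vomeronasal receptors (97 genes, 0.20, 0.021) and beta protocadherins (20 genes, 0.31, 0.034) were higher too, and Nudt hydrolases lower (19 genes, -0.35, 0.033). All 6 kept their direction under median scaling and cyclic loess, and none passed with an estimated correlation (adjusted p = 1.00). Beta protocadherins and Nudt hydrolases no longer passed after local correction (0.26 and 0.080) or without transgenic replicate 4 (0.059 and 0.088), where the other 4 did.

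Sex-biased genes moved in all 3 transgenic livers. For replicate 4, 3 of the 4 Y-linked genes were not above background on that array alone, which is consistent with a female mouse among males, although Kdm5d was not lower there. Replicate 4 alone cannot account for the rest, since the smaller index of replicates 1 and 3 lay 15.4 wild-type SD above the wild-type mean. Patches do not account for it, since that distance was 5.82 SD after local correction. No biological cause was tested, and the transgene, housing, hormones and health of the mice stay open.

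Mt1 and Mt2 were higher in all 3 transgenic livers. Patches do not account for this, since the smaller of both changes was 3.74 ± 0.54 (SE) after local correction. Zinc given to the transgenic mice, which the series text calls possible but seldom needed, could raise both. Slc30a1, another zinc-induced gene, changed by -0.22 with a 95% interval of -0.83 to 0.40, which includes 0 and decides nothing. Stress and inflammation, which also induce metallothioneins, stay open beside the higher acute phase and heat shock lists.

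The Ang probe that was bright in the transgenic group alone is unlikely to report a higher transcript level as a whole, since the other probe of the same transcript changed by 0.47 ± 0.29 (SE). Patches do not account for it, since it lay outside them and its log2 change was 7.29 after local correction. A sequence difference under the probe, carried from another strain with the transgenic line, may be the cause. The probe was the dim one in wild-type livers, at 4.71 to 5.49 against 12.2 to 12.3 in transgenic livers. Such a cause would therefore need a probe that matches the carried sequence and mismatches that of the wild-type mice. The probe's sequence was not used here, so this was not tested. Among the 20 tested genes on each side of Ang, 0% had a large change that separated the groups outside patches. The median of such windows was 0% as well and their 95th percentile 2.5%, since only 27 of 13971 genes had such a change. A short segment could hold no other such probe, so this keeps the question open.

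The design with 3 arrays a group makes 10 splits, too few for a share under 0.05. The real split gave 0 genes higher and 0 lower, and the highest other split 1 and 0. Any split gives at least 0, so the 10 of 10 that gave as many in either direction carry no information. For lists, 4 of the 10 splits gave at least the real 6, and the highest other gave 7.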
